A study of Homo sapiens with 6 samples.

How the data were processed

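RNA was sequenced from PANC-1 cells, an established line of pancreatic epithelioid carcinoma, in which SMAD4 had been knocked out. The sample titles say that these cells were transfected with wild-type (WT) SMAD4 or SMAD4 with the R272K change. There were 3 libraries per group, collected on day 3. Per the labels' protocols, polyadenylated RNA was captured with oligo(dT) beads, fragmented and primed with random hexamers, and whether counting used strand is not given in the sources used here. No library of knockout cells without SMAD4, or with an empty vector, was analysed here. The replicate labels do not say whether libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

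Per the submitters' processing notes, the tools were fastp 0.23.0, HISAT2 2.1.0, SAMtools and HTSeq 0.10.0, with the genome build GRCh38; their settings and the annotation release are not given in the sources used here. The authors deposited raw read counts per gene symbol and, in a separate table, TPM, a length-scaled abundance, for the same libraries. Both tables held 62710 lines for 60835 distinct symbols, because 453 symbols with several identifiers had their value repeated on 1875 extra lines. Each symbol was used once. The deposited TPM values were made from the same counts: the ratio of count to TPM matched between libraries up to 1 scale factor each, with a largest relative deviation of 1.9e-14. They summed to 1296446 to 1472074 as deposited and to 1000000 over distinct symbols. The length that the authors divided by was recovered, up to a constant, from that ratio. Biotypes came from GENCODE release 29, in which the identifiers of 56639 symbols were found; coordinates are those in the deposited tables.

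Total counts over distinct symbols lay between 14776148 and 17706201 per library. Genes were kept by edgeR's expression filter (a minimum count of 10 and a minimum total of 15), which left 15911. Counts were scaled by TMM and tested with edgeR's robust quasi-likelihood test, two-sided, on all 6 libraries with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p below 0.05. Fold changes are log2 of R272K over WT. The standard error (SE) of a log2 fold change is its size divided by the square root of the test's F statistic. Levels are CPM (counts scaled to a common library total) on TMM-scaled library sizes. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.

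28 gene lists were fixed before the data were examined, and some genes belong to several of them. The 24 lists with at least 5 tested genes were compared with all other genes by camera (limma), with its preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Camera with a correlation estimated from the data and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it. Members were also counted with p-values adjusted over the list alone. The rule for named genes, fixed at the same time, took SMAD4 and PRMT1. It added up to 10 higher and 10 lower genes with the largest fold change, among called genes with a mean CPM of at least 1 and no overlap between groups. It also took up to 4 members of each list by smallest p and the most abundant member of lists for other cell types. Genes outside this rule are said to have been chosen after their values were seen. Some genes that the rule takes are not reported here.

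The alternatives, also fixed before the data were examined, were other scalings (RLE, upper quartile, library size only), no filter or a filter of 1 CPM in 3 libraries, DESeq2, limma-voom, the replicate number as a block, each library left out in turn, and limma on log2(TPM + 1) or log2(TPM + 0.1). Added after seeing the data were a fit without SMAD4 and mitochondrial genes, and a fit with each library's trend of expression with gene length removed by a smoothed offset. No 2 libraries of a group agreed within sampling noise: chi-square per degree of freedom between replicates was 1.83 or more.

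The edgeR and camera tests were tested on simulated data for this comparison, a step that runs after the fit to the real counts, with counts for 15911 genes drawn from the libraries' own means and spread and 200 genes changed. The edgeR test recovered 58% of 50 genes changed 1.5-fold, 86% of 50 changed 2-fold, 96% of 50 changed 3-fold and 94% of 50 changed 4-fold, and 12 of its 179 calls were false. Camera found 10 of 10 shifted lists and 0 of 30 unshifted ones, but the simulated genes were drawn independently of each other. On the real counts the 9 other splits of the 6 libraries 3 against 3 gave 3 to 10 lists each with the same preset. These splits mix both groups, so part of a group difference can remain in them. Neither these counts nor the 0 of 30 measures false calls among the lists.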

Results

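Polyadenylated RNA was profiled in SMAD4-knockout PANC-1 cells that carried either WT SMAD4 or the R272K form, in which an arginine is replaced by a lysine. SMAD4 is the shared partner of the receptor-regulated SMADs in TGF-β and BMP signalling, and it is often inactivated in pancreatic cancer. The series addresses methylation of SMAD4 on arginine by the methyltransferase PRMT1, and the comparison asks which transcripts differ when the introduced protein has the substituted residue. Sequencing depth over distinct symbols was 17706201, 14776148 and 15111157 counts in WT replicates 1 to 3. The R272K replicates had 15302222, 15148435 and 15406781.

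SMAD4 itself (ENSG00000141646, chromosome 18, 51028394 to 51085045, GRCh38) was measured in every library. Its level was 83.4, 93.6 and 89.0 CPM in the WT replicates and 40.6, 45.7 and 43.6 CPM in the R272K replicates. The mean fell from 88.7 ± 5.13 to 43.3 ± 2.56 CPM (SD, n = 3 each), a log2 fold change of -1.03 (SE 0.075, adjusted p = 6.28e-06). The counts do not separate any endogenous transcript from the introduced one. SMAD4 level was thus confounded with the group. None of the differences between groups given below can be assigned to the substitution rather than to the amount of SMAD4 or construct. PRMT1 stood at 174.5 ± 19.8 CPM with WT and 174.7 ± 6.78 CPM with R272K SMAD4 (SD, n = 3 each), a log2 fold change of 0.00 (SE 0.079, adjusted p = 0.997).

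Cells with R272K SMAD4 had lower levels of interferon response genes as a set and of the interferon gene IFNL1, and higher levels of CXCL5, CDH1, COL1A1 and SCD. IFIT2, an interferon-induced inhibitor of translation of viral RNA, fell from 142 ± 2.32 to 44.9 ± 1.65 CPM (SD, n = 3 each), a log2 fold change of -1.66 (SE 0.065, adjusted p = 2.14e-08). CDH1, which encodes E-cadherin, rose from 2.59 ± 0.49 to 6.47 ± 0.313 CPM, a log2 fold change of 1.33 (SE 0.177, adjusted p = 0.00174). SCD, the desaturase that makes monounsaturated fatty acids, rose from 538 ± 37.2 to 958 ± 11.8 CPM, a log2 fold change of 0.83 (SE 0.064, adjusted p = 9.72e-06).

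Across the 15911 genes tested, 2270 had an unadjusted p under 0.05 and 193 were called by edgeR's quasi-likelihood test, 109 higher and 84 lower with R272K SMAD4, and 186 of them were protein-coding. A change of at least 2-fold was seen for 29 called genes, of which 6 were higher and 23 lower. The groups did not overlap for 3397 genes, 21.35% of those tested, where chance gives 10%. WT replicate 1 stood apart, at -31.3 on the first principal component (32.2% of variance) against -9.56 to 15.6 for the other libraries. Without it 875 genes were called; without WT replicates 2 or 3 there were 84 and 276, and without R272K replicates 1, 2 or 3 there were 59, 60 and 55. In each of those 6 fits 46 of the 193 genes remained called, 30 of them lower, including SMAD4, IFIT2, CDH1, SCD and COL1A1, and each of the others lost its call in at least 1 of them.

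**Figure D1:**
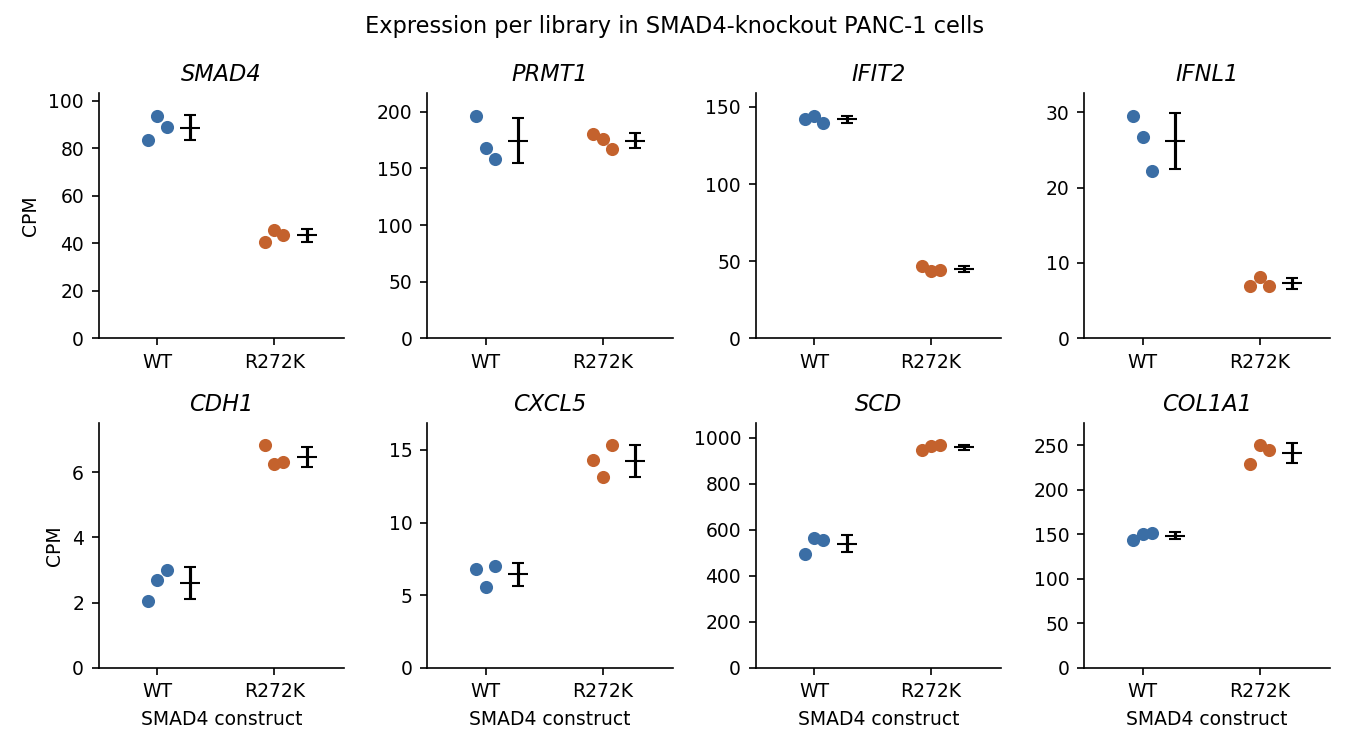
Expression in CPM (vertical axes, from 0) of 8 genes in the 3 libraries of each group (points), with the mean and SD beside them (black). SMAD4, IFIT2 and IFNL1 were lower in every R272K library than in every WT library, CDH1, CXCL5, SCD and COL1A1 were higher, and PRMT1 overlapped.

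The interferon response genes formed the group with the largest number of calls. Of 41 tested members, 19 fell, 0 rose and 22 were not called, and 30 fell when p-values were adjusted over the list alone. IFIT1 fell from 97.5 ± 6.85 to 31.7 ± 1.62 CPM (log2 fold change -1.62, adjusted p = 1.36e-07). IFIT3, of the same family, fell from 71.5 to 29.6 CPM (-1.27, adjusted p = 3.82e-06), and HERC5, a ligase for the ubiquitin-like ISG15, from 30.2 to 10.8 CPM (-1.48, adjusted p = 3.85e-06). The median log2 fold change of the list was -0.54, and camera placed it below other genes (adjusted p = 8.33e-92; adjusted p = 0.000403 with an estimated correlation). Between 12 members, without R272K replicate 1, and 26, without WT replicate 1, were called when 1 library was left out. On the TPM values limma called 10 lower with a pseudocount of 1 or 0.1, and 9 with no filter. SMAD4 transcript was likewise lower in every R272K library.

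Most of the lower genes with the largest changes belonged to the same antiviral programme or encode its ligands. RSAD2, which encodes the antiviral enzyme viperin, fell from 6.98 ± 0.616 to 1.36 ± 0.259 CPM (SD, n = 3 each), a log2 fold change of -2.36 (SE 0.195, adjusted p = 2.11e-05). The oligoadenylate synthetase family members OASL (-1.95, adjusted p = 7.82e-06) and OAS2 (-1.89, adjusted p = 0.000646) fell, as did IFI6 (-1.80, adjusted p = 4.91e-06). The type III interferon gene IFNL1 fell from 26.2 ± 3.74 to 7.3 ± 0.704 CPM (-1.84, adjusted p = 4.91e-06). IFNL3 (-1.91, adjusted p = 2.75e-05) and IFNL2 (-1.78, adjusted p = 8.11e-05) fell as well, but these genes are near-identical and the counting could divide reads between them. IFI44 (-1.85, adjusted p = 0.0145) and the guanylate-binding protein gene GBP5 (-1.71, adjusted p = 0.0359) each lost their call when any 1 R272K library was left out, and GBP5 also without WT replicates 2 or 3. IFNB1, chosen after its values were seen, had 24 counts in the WT libraries together and 4 in the R272K libraries, too few to be tested.

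Among 30 tested NF-κB and cytokine genes, 8 rose, 1 fell and 21 were not called; adjusted over the list alone, 12 rose and 1 fell. CXCL5, a neutrophil chemoattractant, rose from 6.45 ± 0.79 to 14.2 ± 1.1 CPM (log2 fold change 1.14, adjusted p = 0.000372). CXCL1, of the same chemokine class, rose from 194 to 281 CPM (0.54, adjusted p = 0.00171), and the adhesion molecule gene ICAM1 from 824 to 1135 CPM (0.46, adjusted p = 0.00135). The exception was CCL5, a chemokine for T cells that interferon also induces, which fell from 60.2 to 31.3 CPM (-0.95, adjusted p = 7.16e-05). Camera placed the list above other genes (adjusted p = 1.57e-08), with adjusted p = 0.063 with an estimated correlation, and 0.0371 with that correlation and each library's gene length trend removed, an alternative chosen after seeing the data. Members called higher numbered 15 without WT replicate 1, 5 without WT replicate 2 or R272K replicate 1, and 4 without R272K replicates 2 or 3. SELE, which encodes the adhesion molecule E-selectin, rose from 4.21 to 8.2 CPM (0.96, adjusted p = 0.00782), and SERPINA3, an acute-phase protease inhibitor, from 1.4 to 3.27 CPM (1.21, adjusted p = 0.0244).

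Epithelial adhesion genes were higher as a set (camera adjusted p = 4.04e-07; adjusted p = 0.0321 with an estimated correlation). Of 30 tested, 3 rose, 0 fell and 27 were not called; 9 rose and 1 fell when adjusted over the list alone. Beside CDH1 these were CDH3, which encodes P-cadherin and rose from 2.74 to 5.39 CPM (0.97, adjusted p = 0.0244), and SPINT1, a membrane inhibitor of serine proteases (0.50, adjusted p = 0.0324). Keratin gene KRT8 stood at 2237 and 2795 CPM (adjusted p = 0.0661). With WT replicate 1 left out, 11 members were called higher and 1 lower, whereas 2 were higher without WT replicate 3 and 1 without WT replicate 2 or any R272K library. The mesenchymal list was also higher as a set (adjusted p = 0.00281; adjusted p = 0.172 with an estimated correlation). Its 29 tested members included 2 that rose, COL1A1 and FN1, 0 that fell and 27 not called, and 6 rose and 1 fell adjusted over the list alone. COL3A1 (0.50, adjusted p = 0.0665) and COL5A1 (0.30, adjusted p = 0.131) were not called. Chosen after their values were seen, VIM (adjusted p = 0.927), CDH2 (adjusted p = 0.98) and ZEB1 (adjusted p = 0.719), a filament protein, a cadherin and a repressor of CDH1 linked to the mesenchymal state, were not called. Mesenchymal members called higher numbered 6 without WT replicate 1 and 1 without R272K replicates 1 or 3.

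Matrix and integrin genes were higher as a set (camera adjusted p = 3.61e-09), a call lost with an estimated correlation (adjusted p = 0.224). Among 45 tested, 4 rose, 0 fell and 41 were not called; 15 rose and 1 fell adjusted over the list alone. COL1A1, the main chain of type I collagen, rose from 149 ± 3.91 to 241 ± 11.2 CPM (0.70, adjusted p = 3.51e-05). The fibronectin gene FN1 rose from 60.9 to 91.1 CPM (0.58, adjusted p = 0.0054), with COL5A2 (0.41, adjusted p = 0.00782) and ITGB8 (0.43, adjusted p = 0.046). These are long genes, with a median relative length of 2.19, and in WT replicate 1 the log2 ratio to the other WT libraries fell with gene length (Spearman's rho -0.41 across genes, which are not independent replicates). Without that library 13 were called higher and 2 lower, and camera still placed the list above other genes (adjusted p = 6.31e-07). Leaving out R272K replicate 2 gave 2 higher, and R272K replicates 1 or 3 gave 1. With each library's length trend removed, an alternative chosen after seeing the data, the list median went from 0.17 to 0.14. Camera placed the list above other genes there too (adjusted p = 1.3e-07), but not with an estimated correlation (adjusted p = 0.0792).

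Targets of TGF-β and SMAD signalling went both ways, with 5 of 36 tested genes higher, 1 lower and 30 not called; adjusted over the list alone, 7 were higher and 3 lower. COL1A1 and FN1 were joined by TGFBI, a secreted matrix protein gene, which rose from 280 to 366 CPM (0.39, adjusted p = 0.0052), and PODXL, a sialomucin gene (0.33, adjusted p = 0.0339). As a set the list lay above other genes (camera adjusted p = 0.0075), with adjusted p = 0.221 with an estimated correlation. 3 genes often used as readouts of the pathway, chosen after their values were seen, were not called. SMAD7, the inhibitory SMAD, stood at 20 and 19.3 CPM (adjusted p = 0.817), SKIL at 147 and 162 CPM (adjusted p = 0.469) and CDKN1A at 167 and 166 CPM (adjusted p = 0.944). When WT replicate 1 was left out, 9 targets were higher and 3 lower; without WT replicate 2 or R272K replicates 1 or 2, 2 were higher, and without R272K replicate 3, 1.

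Of 35 listed pathway components 0 were called, and 1 was lower adjusted over the list alone. Called but not in the list were SMAD4 and, chosen after its values were seen, the ligand gene BMP5. Of the 35, 15 had an unadjusted p under 0.05, and DESeq2 called 1 and limma-voom 0. Camera gave an adjusted p of 0.0893, 0.0416 with limma-voom on all 6 libraries, and 0.0364 and 0.0454 without WT replicates 2 and 3, with estimates on balance upward. With an estimated correlation on all 6 libraries the adjusted p was 0.55. GDF15, a stress-induced member of the TGF-β family, had the smallest p (-0.31, adjusted p = 0.0754). BMP targets gave 0 calls among 17 tested, 0 with DESeq2 or limma-voom, 3 at an unadjusted p under 0.05 and 1 lower adjusted over the list alone (camera adjusted p = 0.396), with MSX2 at -0.63 (adjusted p = 0.107). Arginine methylation genes gave 0 calls among 17, also with limma-voom, 1 with DESeq2, 3 at an unadjusted p under 0.05 and 1 lower adjusted over the list alone. Camera gave an adjusted p of 0.057 for them, and 0.0208, 0.0453 and 0.03 without WT replicate 3, R272K replicate 2 and R272K replicate 3, downward. On all 6 libraries it was 0.0341 with limma-voom, 0.0133 with no filter and 0.0491 with the replicate number as a block. These values are at the preset correlation. With an estimated correlation it was 0.397, and 0.254 with the length trend also removed, an alternative chosen after seeing the data. SMN1, a reader of methylated arginine that shares reads with a near-identical copy, stood at -0.56 (adjusted p = 0.0883) and PRMT5 at -0.16 (adjusted p = 0.347). With WT replicate 1 left out, 2 components, 1 BMP target and 1 arginine methylation gene were called lower, and without WT replicate 3, 1 component and 1 arginine methylation gene.

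Proteases linked to invasion did not move as a set (31 tested, camera adjusted p = 0.502), with 2 lower, 0 higher and 29 not called; adjusted over the list alone, 6 were higher and 4 lower. MMP1, the interstitial collagenase gene, fell from 55.6 ± 6.36 to 24.2 ± 1.06 CPM (-1.20, adjusted p = 9.72e-06), and kept its call without each library. The lysosomal protease gene CTSL fell from 138 to 102 CPM (-0.43, adjusted p = 0.0136), while ADAM9 (0.28, adjusted p = 0.061) and PLAU (0.24, adjusted p = 0.0841) were not called. In the fit lacking WT replicate 1, 5 were higher and 2 lower, and without WT replicate 2 or R272K replicates 1 or 3 there was 1 lower. Of 23 targets of YAP and TEAD, 2 fell, 0 rose and 21 were not called; 3 fell and 1 rose adjusted over the list alone. They were ANKRD1, an ankyrin repeat protein gene (-0.56, adjusted p = 0.000469), and GADD45A, a stress-induced growth arrest gene (-0.47, adjusted p = 0.0179). The median of that list was 0.05, its mean -0.02 and the direction of camera downward (adjusted p = 0.903). After removal of WT replicate 1, 3 of them were lower and 2 higher, and 1 was lower without WT replicate 2 or any R272K library.

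**Figure D2:**
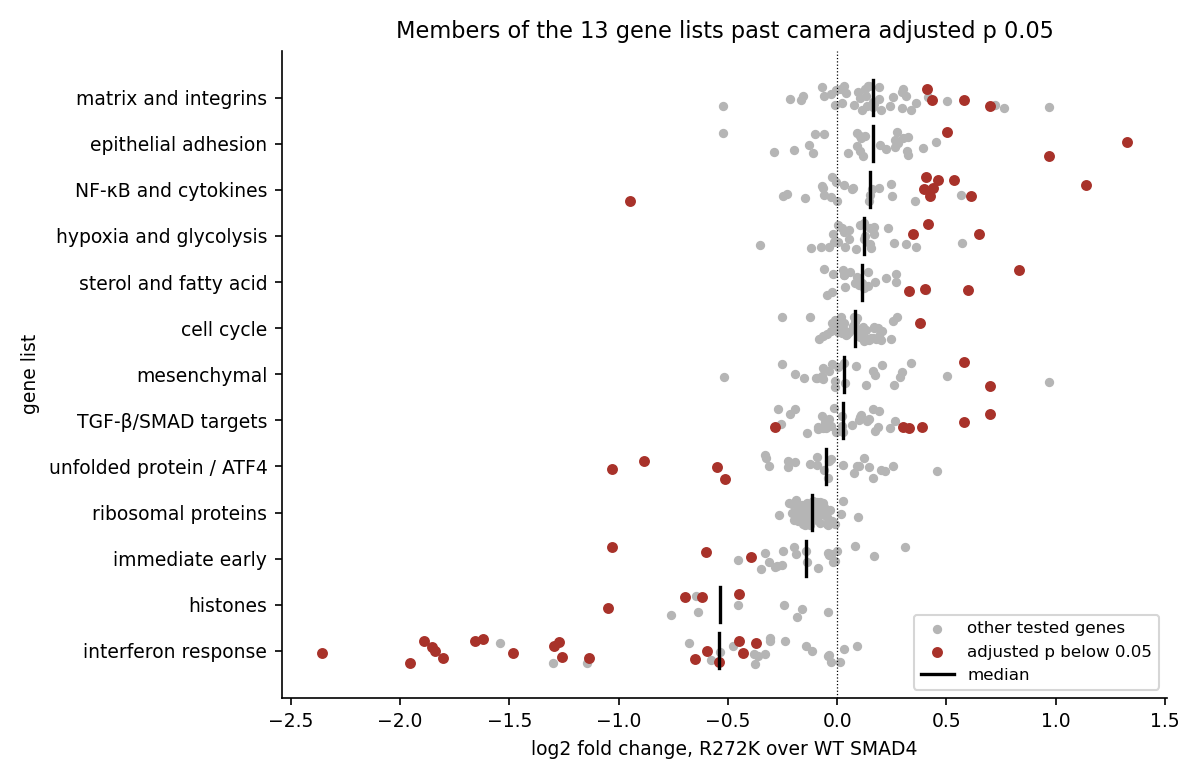
Log2 fold change of R272K over WT SMAD4 (horizontal axis) for each tested member of the 13 lists past camera adjusted p 0.05, with called genes in red and list medians as black lines. The interferon list has 19 called members, all below 0, and the NF-κB list 8 above 0 and 1 below.

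Immediate early genes were lower as a set (camera adjusted p = 6.23e-08; adjusted p = 0.172 with an estimated correlation). Of 27 tested, 3 fell, 0 rose and 24 were not called; 9 fell adjusted over the list alone. ATF3, a stress-induced transcription factor gene, fell from 33.9 ± 2.56 to 16.6 ± 0.705 CPM (-1.03, adjusted p = 3.2e-05). The transcription factor gene EGR1 (-0.60, adjusted p = 0.00469) and the phosphatase gene DUSP5 (-0.40, adjusted p = 0.0102) fell too, and FOSL1 was not called (-0.27, adjusted p = 0.0599). With WT replicate 1 left out, 6 were lower, without WT replicate 3, 5, without R272K replicate 1, 1, and without any other library, 2. The unfolded protein and ATF4 list was lower as well (camera adjusted p = 0.000409; adjusted p = 0.397 with an estimated correlation). Among 28 tested, 4 fell, 0 rose and 24 were not called; 7 fell and 1 rose adjusted over the list alone. Beside ATF3 these were PPP1R15A, which directs dephosphorylation of the initiation factor eIF2 (148 to 101 CPM, -0.55, adjusted p = 0.000471), the amino acid transporter subunit gene SLC3A2 (-0.51, adjusted p = 0.00174) and the pro-apoptotic factor gene DDIT3 (-0.89, adjusted p = 0.0038). Without WT replicate 1 this list held 5 higher and 5 lower, and without WT replicate 3, 6 lower. Heat shock genes gave 0 calls among 13, also adjusted over the list alone or with DESeq2 or limma-voom. At an unadjusted p under 0.05 there was 1. Camera gave an adjusted p of 0.146, 0.0281 without WT replicate 3, and 0.577 with an estimated correlation on all libraries. HSPE1 stood at -0.40 (adjusted p = 0.151).

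Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, were lower as a set (camera adjusted p = 2.59e-11; adjusted p = 0.0727 with an estimated correlation). Of 12 tested, 4 fell, 0 rose and 8 were not called; 8 fell adjusted over the list alone. H4C8 fell from 9.91 ± 1.49 to 4.8 ± 0.479 CPM (-1.05, adjusted p = 0.0034) and H2AC6 from 29.2 to 18.1 CPM (-0.70, adjusted p = 0.00744), with H1-2 (-0.62, adjusted p = 0.025) and H2BC5 (-0.45, adjusted p = 0.0396). When WT replicate 1 was left out, 7 were lower; without R272K replicate 1 there were 2, and without R272K replicates 2 or 3, 1. Histone genes are short, with a median relative length of 0.26. With the length trend of each library removed, an alternative chosen after seeing the data, the list median went from -0.54 to -0.46 and the adjusted p with an estimated correlation was 0.0181. Ribosomal protein genes were lower as a set (camera adjusted p = 6.23e-05), with adjusted p = 0.577 with an estimated correlation and 0 of 59 called, also adjusted over the list alone or with DESeq2 or limma-voom; 4 had an unadjusted p under 0.05. RPL11 stood at -0.27 (adjusted p = 0.186). These genes took 3.99% of counts in WT replicate 1 and 3.01% to 3.27% in the other libraries. Without that replicate the direction of the list turned (adjusted p = 0.706).

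Cell cycle genes were slightly higher as a set, with a median log2 fold change of 0.08 (camera adjusted p = 0.000278; adjusted p = 0.0591 with an estimated correlation, and 0.0181 when the length trend was also removed). CENPF, a kinetochore protein gene, was the only call among 45 tested (374 to 487 CPM, 0.38, adjusted p = 0.0381), and 44 were not called; 5 rose adjusted over the list alone. In the fit lacking WT replicate 1, 12 were higher, without WT replicate 3, 2, and without any 1 R272K library, 0. Of 24 tested inhibitors of cyclin-dependent kinases and apoptosis genes, GADD45A alone fell and 23 were not called, also adjusted over the list alone (camera adjusted p = 0.366). After removal of WT replicate 1, 2 were lower, and without WT replicate 2 or any R272K library, 0. PMAIP1, a p53 target that promotes apoptosis, stood at -0.22 (adjusted p = 0.138).

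Sterol and fatty acid genes were higher as a set (camera adjusted p = 3.61e-09; adjusted p = 0.0321 with an estimated correlation). Of 25 tested, 4 rose, 0 fell and 21 were not called; 8 rose adjusted over the list alone. Among them were SCD, its regulator SREBF1, which encodes a sterol-responsive transcription factor (65 to 98.3 CPM, 0.60, adjusted p = 0.000629), and the fatty acid synthase gene FASN (0.33, adjusted p = 0.037). With WT replicate 1 left out, 7 were higher, and without any 1 R272K library, 2. Hypoxia and glycolysis genes were higher as well (camera adjusted p = 3.09e-06; adjusted p = 0.105 with an estimated correlation). Among 31 tested, 3 rose, 0 fell and 28 were not called; 4 rose adjusted over the list alone. PFKFB4, which makes the activator of phosphofructokinase, rose from 34.4 to 53.9 CPM (0.65, adjusted p = 0.000664), with the phosphofructokinase gene PFKL (0.35, adjusted p = 0.0244) and the pyruvate dehydrogenase kinase gene PDK1 (0.41, adjusted p = 0.0452). When WT replicate 1 was left out, 7 were higher, and without WT replicate 2 or any R272K library, 1.

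Secreted growth and guidance factors did not pass as a set (28 tested, camera adjusted p = 0.0893), although 3 rose, 1 fell and 24 were not called; 4 rose and 1 fell adjusted over the list alone. IGFBP6, a binding protein for insulin-like growth factors, fell from 17.3 to 10.5 CPM (-0.72, adjusted p = 0.00356), while the guidance cue genes SEMA3A (0.45, adjusted p = 0.0038) and EFNA1 (0.48, adjusted p = 0.00782) rose. With the length trend removed, an alternative added after seeing the data, the set passed at the preset correlation (adjusted p = 0.0298). With an estimated correlation the set did not pass there (adjusted p = 0.12) or in the main fit (adjusted p = 0.221). At the preset correlation the set also passed without WT replicate 1 (adjusted p = 0.0105), with 5 higher. Without WT replicate 2 or R272K replicates 1 or 2, 1 was higher, and without the others, 2. WNT targets gave 0 calls among 13, also adjusted over the list alone or with DESeq2 or limma-voom, and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.521), with AXIN2 at 0.22 (adjusted p = 0.409). Pancreatic ductal genes gave 0 calls among 11, 1 with DESeq2, 0 with limma-voom, 3 at an unadjusted p under 0.05 and 1 higher adjusted over the list alone (camera adjusted p = 0.521). Leaving WT replicate 1 out gave 1 higher, and SOX9, a ductal transcription factor gene, stood at 0.24 (adjusted p = 0.0613). Genes encoded in mitochondria gave 0 calls among 13, also adjusted over the list alone or with DESeq2 or limma-voom, and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.911), with a mean of -0.01, a median of 0.01 and an upward direction. In the fit lacking WT replicate 1, 5 of them were called higher and the set passed at the preset correlation of 0.01 (adjusted p = 0.00119). On all 6 libraries the correlation estimated for this list was 0.412, and with it the adjusted p was 0.964. MT-ND5, a subunit of complex I, stood at 0.13 (adjusted p = 0.304).

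Markers of other cell types were mostly below the expression filter, and DESeq2 and limma-voom also called 0 of the tested leukocyte, endothelial, acinar and endocrine markers; at an unadjusted p under 0.05 there was 1 endothelial marker and 0 of the rest. Of the leukocyte list 2 of 12 were tested and 0 called, also adjusted over the list alone, and its most abundant member ITGAM stood at 5.52 and 5.53 CPM (adjusted p = 0.995). Endothelial markers gave 2 tested of 10 and 0 called, also adjusted over the list alone, with ESAM at 18.4 and 15.6 CPM (adjusted p = 0.31). Acinar and endocrine markers gave 2 tested of 13 and 0 called, also adjusted over the list alone, with SYP at 12 and 10.3 CPM (adjusted p = 0.465). Of 12 fibroblast markers 4 were tested: COL1A1, their most abundant member, rose, 3 were not called, and 2 rose adjusted over the list alone. DESeq2 called 2 of them and limma-voom 1, and with no expression filter the fibroblast list passed camera as a set. COL1A2, the partner chain of COL1A1 in fibroblasts, stood at 0.45 and 0.875 CPM (adjusted p = 0.449), and COL3A1 at 10.1 and 14.3 CPM.

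The remaining higher genes with the largest changes belonged to no common list. FAM13A rose from 1.04 to 2.68 CPM (1.34, adjusted p = 0.0359), the prostacyclin synthase gene PTGIS from 3.23 to 5.83 CPM (0.85, adjusted p = 0.0374) and CREB3L3, a membrane-bound transcription factor gene, from 3.99 to 7.16 CPM (0.83, adjusted p = 0.0432). All 3 lost their call without WT replicate 2 or any 1 R272K library, and CREB3L3 also without WT replicate 3. CNTNAP3C rose from 2.93 to 7.37 CPM (1.34, adjusted p = 0.0209), but it has close paralogs that the counting could not separate with certainty. Its level was 5.97, 5.46 and 10.7 CPM in R272K replicates 1 to 3, and it also lost its call in at least 1 fit without 1 library. RN7SL5P (chromosome 9, 9442060 to 9442380), a copy of the RNA component of the signal recognition particle, had 2, 0 and 2 counts in the WT replicates and 108, 97 and 53 in the R272K replicates (adjusted p = 2.6e-05). Its sequence is shared with many near-identical copies, so the source of these reads is uncertain.

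**Figure D3:**
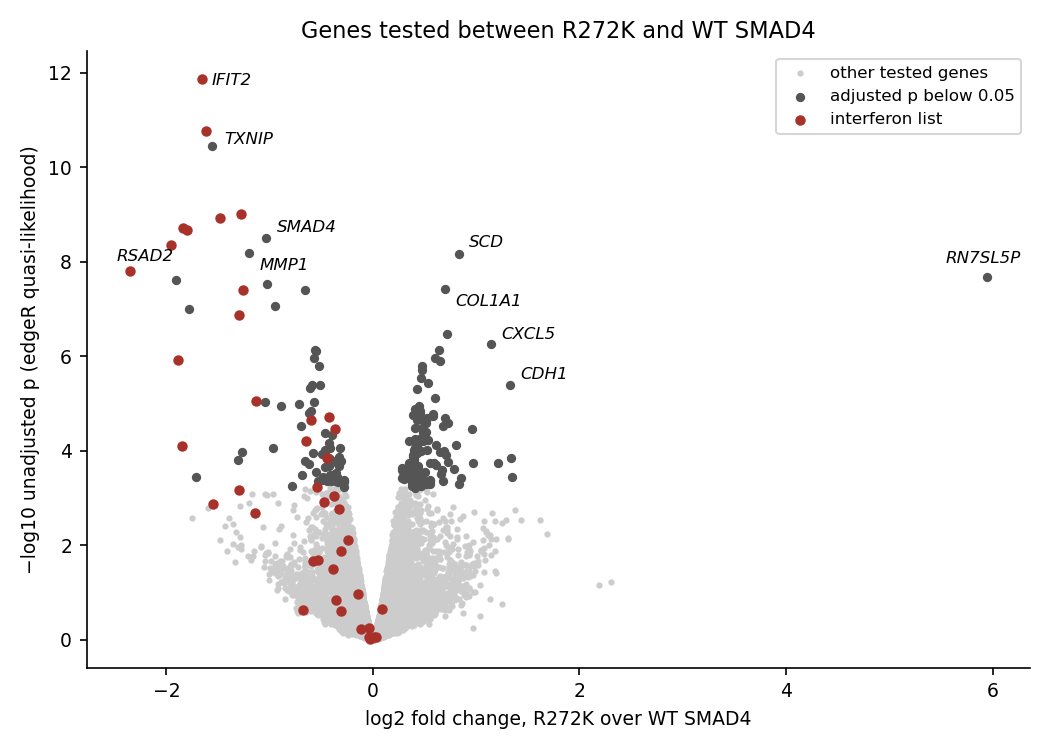
Log2 fold change of R272K over WT SMAD4 (horizontal axis) against the negative log10 of the unadjusted p (vertical axis) for the 15911 genes tested, with interferon list members in red and other called genes in dark grey. IFIT2 has the smallest adjusted p (2.14e-08), and SMAD4 lies at -1.03.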

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

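The fits without SMAD4 and mitochondrial genes and with the gene length trend removed were chosen after seeing the data; the others were fixed before. In each fit to counts or TPM values, those of the 193 called genes that it measured had the same sign. Without SMAD4 and mitochondrial genes 193 were called (109 higher, 84 lower, 28 at least 2-fold), 192 of them among the first 193, which leaves out only SMAD4. SMAD4 was past the threshold in all 18 alternatives (log2 fold change -1.10 to -0.97, highest adjusted p 0.0314). With other scalings, 193 (RLE), 188 (upper quartile) and 189 (library size only) of the calls remained, and 190 with limma-voom, with DESeq2 and with the 1 CPM filter. Library size alone gave 213 calls, 50.2% of them higher against 56.5%. DESeq2 called 279 genes, 146 higher and 133 lower. With no filter, 474 genes were called of 36623 tested, 466 of them within the 15911 genes of the comparison, 227 higher, 247 lower and 47 at least 2-fold; the cause was not tested. On the TPM values, limma called 61 genes (29 higher, 32 lower) with a pseudocount of 1, 55 (24 and 31) with 0.1, and 37 (12 and 25, 19 at least 2-fold) with no filter; the cause was not tested. Leaving out 1 library gave 55 to 875 calls, 21 to 480 higher and 33 to 395 lower, the highest without WT replicate 1 and the lowest total without R272K replicate 3, with fewer samples in each fit. With the length trend removed, 619 were called (319 higher, 300 lower), including all 193.

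Of the 13 lists, 3 passed with an estimated correlation (interferon, epithelial adhesion, sterol and fatty acid) and 10 with fry. When the length trend was removed as well, those 3 still passed, with the NF-κB, cell cycle and histone lists in addition. The rest of the 13 did not pass there. Adjusted p was 0.0792 for the matrix, immediate early and hypoxia lists and 0.0915 for the mesenchymal list. It was 0.204 for TGF-β targets, 0.225 for the unfolded protein list and 0.683 for ribosomal proteins. Of all lists tested, 13 to 16 passed in each of the other alternatives fixed before, and these held all 13 except without WT replicate 1 (14 passed, 12 of them among the 13, ribosomal proteins lost). Lists were not tested with DESeq2 or on TPM values. Over list results, 10 of 24 were weaker with the estimated correlation and 3 of 24 with fry. Arginine methylation genes passed in 6 alternatives, among them the one with no filter, all at the preset correlation. Directions turned for YAP and TEAD targets with limma-voom (camera adjusted p = 0.707) and without WT replicates 2 or 3. Over the 6 fits with 1 library left out, the adjusted p of that list ranged from 0.388 to 0.979. Mitochondrial genes turned with no filter (0.993), without WT replicates 2 (0.766) or 3 (0.309), and without R272K replicate 2 (0.407). Their range over the 6 was 0.00119 to 0.936, and the lowest value, without WT replicate 1, kept the upward direction. Ribosomal protein genes turned without WT replicate 1, with the highest adjusted p of the 6 such fits (1.8e-14 to 0.706). For 115 named genes, 101 of 690 values without 1 library were weaker, 26 stronger and 12 reversed. The reversals were in genes that were not called: PRMT1 (-0.067 to 0.096 over fits without 1 library; with library size only -0.006, with no filter -0.002), CD14 (-0.111 to 0.304), ITGAM (-0.066 to 0.068; library size only -0.005, length trend removed -0.014), KDR (-0.262 to 0.021) and MT-ATP6 (-0.183 to 0.047); the cause was not tested.

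The labels state no pairing of samples by replicate number. Deviations from group means correlated at -0.065, -0.007 and -0.012 between libraries of the same number. No library correlated best with its own number. With 3 libraries per group these correlations show no pairing but cannot exclude it. With the number as a block, 262 genes were called, 187 of them among the 193, and 14 lists passed, the arginine methylation list in addition. At this depth the simulated test recovered 58% of 1.5-fold changes, and 71 of the 193 called genes changed at least 1.5-fold.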

Other observations

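The tests of scaling, of gene length and of depth were chosen only after the result was seen, as were the annotation terms and the genes named in this paragraph, the next and the last. Several called genes outside the fixed lists had values as distinct as those within them. TXNIP, an inhibitor of thioredoxin that also limits glucose uptake, fell from 49.6 ± 1.7 to 16.8 ± 0.762 CPM (SD, n = 3 each; log2 fold change -1.56, edgeR adjusted p = 1.92e-07), and its paralog ARRDC4 stood at -0.67 (adjusted p = 0.061). CYP1B1, which the aryl hydrocarbon receptor can induce, fell from 546 to 346 CPM (-0.66, adjusted p = 3.51e-05), TIPARP from 176 to 118 CPM (-0.57, adjusted p = 0.000629) and CYP1A1 from 5.85 to 3.4 CPM (-0.78, adjusted p = 0.0465); the targets of that receptor were not tested as a set. The receptor gene AHR stood at 89.8 and 89.6 CPM (adjusted p = 0.99), and its repressor AHRR at -0.50 (adjusted p = 0.497). HMOX1, the haem oxygenase induced by oxidative stress, fell from 38.4 to 25.2 CPM (-0.61, adjusted p = 0.0019), with the ferritin light chain gene FTL (-0.40, adjusted p = 0.0381); NQO1 (adjusted p = 0.083) and GCLM (adjusted p = 0.45), other targets of the same stress response, were not called. SLC12A2, a sodium, potassium and chloride cotransporter gene, rose from 249 to 388 CPM (0.64, adjusted p = 0.000469), and BMP5, a ligand of the BMP pathway, from 25.7 to 39 CPM (0.60, adjusted p = 0.00292).

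Of 5026 hypergeometric tests of deposited annotation terms against the annotated tested genes (11660 for processes, 5293 for pathways), 41 passed an adjusted p of 0.05, 23 for higher and 18 for lower genes. These tests use the calls already described and treat genes as independent, so correlation between genes can make their p-values too small. Lower genes held 21 of 157 genes of the defence response to virus (adjusted p = 1.02e-18). Higher genes held 7 of 18 genes of chemokine-mediated signalling (CCL20, CX3CL1, CXCL1, CXCL2, CXCL3, CXCL5 and CXCL8; adjusted p = 1.08e-07). They also held 14 of 256 cell adhesion genes (adjusted p = 3.24e-05), 13 of 219 genes of the inflammatory response (adjusted p = 3.46e-05) and 9 of 91 of extracellular matrix organisation (adjusted p = 4.93e-05). Lower genes held 3 of 10 genes of oestrogen metabolism (adjusted p = 0.00647). They were CYP1A1, CYP1B1 and TIPARP, the same 3 calls named in the preceding paragraph, so the term adds no separate finding. The lowest adjusted p for a share of called genes on 1 chromosome was 0.672.

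The 10 ways to divide the 6 libraries 3 against 3 are too few for a share under 0.05. In edgeR's test 1 of the 10 splits, the real one, gave as many called genes: 193 against a highest other count of 0, where the other splits had 295 to 916 genes at an unadjusted p under 0.05. Likewise 1 of 10 gave 29 genes of at least 2-fold (highest other 0), and 1 of 10 gave 13 lists (the other splits 3 to 10).

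The lower interferon genes in R272K cells did not rest on 1 library. The mean log2 CPM of the list was 3.988 to 4.026 in the WT libraries and 3.163 to 3.255 in the R272K libraries. At the preset correlation, the highest camera adjusted p over the 6 fits with 1 left out was 1.12e-75, against 8.33e-92 with all 6. The lower interferon genes did not depend on the choice among these scalings either: the list median nearest to 0 over 3 other scalings was -0.531. Those scalings differed little, with a median over all tested genes of -0.009 to 0.009, so they could shift the list little. A hypothesis is that introduced nucleic acid or construct amount, rather than the substitution, could set the interferon level, since SMAD4 transcript was lower in all R272K libraries. Within groups, the library with the most SMAD4 minus that with the least differed in mean interferon log2 CPM by -0.038 with WT (SD 0.022, n = 3) and 0.029 with R272K SMAD4 (SD 0.047, n = 3), so construct amount and substitution, which also stays open, cannot be told apart: SMAD4 level is confounded with the group.

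WT replicate 1 stood apart from the other libraries, including its own group. Its greater depth, which acts through counting noise, does not account for this: over 3482 genes with at least 1001 counts in each library, the SD of its log2 ratio to WT replicates 2 and 3 was 0.203 and 0.24, at least 2.28 times the highest of the 4 other pairs within a group (0.0622 to 0.0893). A trend with gene length may account for part of it, as its log2 ratio to the other WT libraries fell with length across genes (Spearman's rho -0.409). Across genes, the log2 fold change of the comparison had a rho of 0.202 with length, and -0.003 without that library. With the trend removed it was -0.009, a value near 0 that the removal itself brings about. All 193 calls remained there among 619. What gave that library its trend, such as RNA integrity or fragment selection, was not tested, and no biological explanation was tested.

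RN7SL5P rose in R272K libraries while RNAs of the same kind were not called. Had more such RNA carried over into the R272K libraries, RN7SL1 and RMRP could be expected to be higher too. The median log2 fold change of these 2, the only ones counted of 5 chosen, was -0.057. That argues against a carry-over as large as the rise of RN7SL5P (log2 fold change 5.95). A smaller one cannot be excluded with 2 RNAs, of which RN7SL1 varied widely within groups. The groups had 6863 and 6223 counts of RN7SL1, with 994 to 3845 per library, and 131 and 124 of RMRP. All 680 copies of the family together had 9070 counts in WT and 8546 in R272K libraries. How reads were divided among the near-identical copies, or whether the introduced construct holds a similar sequence, stays open and untested.

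Higher activity of the liver X receptor was considered for the sterol and fatty acid genes, because ABCA1 (48.9 to 80.7 CPM, 0.73, adjusted p = 0.00663) and LPCAT3 (0.55, adjusted p = 0.0244), both its targets, rose. Over 10 tested of 12 other targets the median log2 fold change was 0.05 (SD 0.252; 6 above and 4 below 0), with a two-sided permutation p of 0.492 against random lists matched on expression. The bound written before the test, a median below 0.1, was met by less than the SD of the targets, and the set left out the called ABCA1 and LPCAT3, so higher receptor activity stays open; ABCG1 (0.58) and MYLIP (0.26) were not called.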
